A study of Mus musculus with 4 samples.

How the data were processed

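Total RNA of lymph node B cells from 2 wild type and 2 miR-146a transgenic mice was measured on Affymetrix arrays with perfect-match (PM) probe sets. Per the labels' protocols, B cells were isolated by magnetic depletion of other cells ("untouched"), dead cells were removed, and biotin-labelled RNA was prepared with a kit that primes at the 3' end. The deposited table holds log2 signals made by the authors, 1 value for each of 45141 probe sets and array. How the authors corrected the background, normalized and summarised the probes is not given in the sources used here. The log2 scale was read from the values, which reach 13.03, since natural logarithms of that size would exceed a 16-bit scanner's range. The columns' distributions were near but not equal (medians 4.48 to 4.61), which does not tell how the probes were normalized. The lower signal of transgenic mouse 1 entered the fits as deposited. Detection calls and scanner files were not used here, so low values have no background flag. Non-specific control probe sets of 10 to 20 G or C bases averaged 2.83 to 2.95, and folds against values near that level understate the change.

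Groups were taken from the sample titles. The labels number the mice 1 and 2 in each group but tie no wild type mouse to a transgenic one, and the same-numbered arrays did not deviate together (correlation of deviations across probe sets 0.01), so the main fit has no replicate block. Gene names came from the platform annotation: 28898 probe sets carried 1 gene, 551 several and 15588 none, and 28689 of the 28898 were matched by Entrez ID to RefSeq genes of GRCm38.p6, which changed no symbol. No coordinates are printed, since the deposited values name no genome build. Each of 17097 genes was represented by its probe set with the highest mean over the 4 arrays. The 104 control probe sets were left out of the tests.

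Transgenic and wild type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over 45037 probe sets, threshold 0.05, 2 residual degrees of freedom per probe set and 2.69 prior degrees of freedom). In data simulated from the arrays' means with variances drawn from the fitted prior, the same fit recovered 4% of 50 changes of 1 log2 unit, 76% of 50 changes of 2, 94% of changes of 3 and 100% of changes of 4, with 11 false calls among the other probe sets. Single genes that changed about 2-fold would therefore mostly be missed. Gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01, Benjamini-Hochberg over 21 lists). On simulated genes, drawn independently of each other, 29 of 1000 random lists had p under 0.05. That check does not cover lists whose genes move together. An estimated correlation was the alternative, and no list passed with it. The estimates ran from 0.075 (stroma and endothelium) to 0.894 (NF-kB and Toll-like receptor components). With an estimated correlation camera takes its degrees of freedom from the arrays, 2 here, and not from the number of genes. A list could therefore hardly pass, so these p-values cannot tell whether correlation between genes accounts for a list's call. Fry, which tests whether a list's genes move one way without reference to other genes, gave its smallest adjusted p, 0.127, for neutrophils (unadjusted p = 0.00604). Camera compares a list with all other genes, so its direction can differ from the median or mean: it was higher for stroma and endothelium (median -0.02, mean -0.01), for erythroid cells and platelets (mean -0.01) and for apoptosis (mean -0.08).

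The named genes were fixed by a rule: per direction, up to 12 genes past the threshold with no overlap between groups, ordered by size, filled with the smallest p among non-overlapping genes that changed by at least 1 log2 unit; 10 genes of miR-146a biology whatever their values; and at most 4 members of every other list by smallest p. One of the 10 genes is not reported here. Alternatives fixed in advance were the replicate block, quantile normalization, median centring, a filter that keeps probe sets above the 40th percentile of mean signal (4.10), a trended and robust eBayes, other thresholds, the mean of all probe sets per gene, the estimated correlation, and leaving out each array. The miR-146a seed test was not run, because 3' untranslated region sequences were not used here, and the pseudocount alternatives did not apply to log2 values. The limma p-values rest on the spread between 2 mice per group, shared across probe sets. Camera p-values with the preset correlation and permutation p-values over genes compare genes with other genes, so their units are genes and not mice. Figures were drawn with matplotlib 3.10.9.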

Results

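Gene expression was profiled in B cells from the lymph nodes of male Balb/C mice, an inbred laboratory strain. The mice were wild type or carried a transgene that over-expresses miR-146a, a microRNA known as a brake on Toll-like receptor and NF-kB signalling. Each group held 2 mice with 1 Affymetrix array per mouse, 4 arrays in all, and 45037 probe sets were compared after 104 control probe sets were set aside. The deposited values were log2 signals between 2.01 and 13.03. The 2 wild type arrays lay close together (Pearson r = 0.9984 across probe sets, SD of their difference 0.12), and the 2 transgenic arrays lay further apart (r = 0.9893, SD 0.32). The array of transgenic mouse 2 was closer to both wild type arrays (r = 0.9912 and 0.991, SD 0.278 and 0.282) than to that of transgenic mouse 1. The array of transgenic mouse 1 had a lower median (4.48) and upper quartile (6.14) than the other 3, whose medians were 4.59 to 4.61 and whose upper quartiles were 6.51 to 6.56. On that array the signal of beta-actin at the 3' end exceeded that in the middle of the transcript by 0.47, against 0.14 to 0.16 on the other 3. Its excess over the 5' end was 0.38 there and 0.16 to 0.28 on the other 3, but for Gapdh the excess of the 3' over the 5' end was 0.018 there, below both wild type arrays (0.075 and 0.093). Precision is limited by the number of arrays. With 2 against 2, an exact permutation test of a single gene cannot give a two-sided p below 0.333, so genes were tested with limma, which shares the spread across probe sets.

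The first question was which transcripts differed between transgenic and wild type B cells. Of the 45037 probe sets, 21 passed an adjusted p of 0.05 by limma with Benjamini-Hochberg adjustment, 17 of them higher and 4 lower in the transgenic arrays. Single genes were named for 10 of these probe sets and stood for 9 genes. Chil3, a chitinase-like protein of myeloid cells (probe set 1419764_PM_at), rose from 3.88 ± 0.14 to 7.71 ± 0.13 (SD, n = 2 each), a 14.3-fold change (log2 change 3.83, SE 0.13, limma adjusted p = 0.0219). Ngp, a neutrophil granule protein (1418722_PM_at), rose 6.83-fold (log2 change 2.77, SE 0.11, limma adjusted p = 0.0219). Stac3, an adaptor protein best known from skeletal muscle (1458087_PM_at), rose 14.2-fold (log2 change 3.83, SE 0.18, limma adjusted p = 0.0307). Apol7b, of the apolipoprotein L family (1436271_PM_at), rose 5.81-fold, and Gcc2, a Golgi coiled-coil protein (1429081_PM_at), rose 4.71-fold. Gcc2 did not pass as the mean of its 2 probe sets (log2 change 0.93, limma adjusted p = 0.0685), and the other one, at 3.61 in the wild type arrays, differed by -0.37. Xist, the RNA that silences an X chromosome in female cells (1436936_PM_s_at), rose 9.64-fold. Mfap1a rose 14.2-fold on 1 probe set (1419370_PM_a_at, log2 change 3.82, limma adjusted p = 0.0359). It was named after its values were seen, because its brightest probe set (mean 7.48) did not pass (log2 change 1.03, limma adjusted p = 0.149), nor did the third (log2 change 3.02, adjusted p = 0.0597). Pld4, a phospholipase D family member (1433678_PM_at), fell 3.81-fold, from 8.55 to 6.62 (log2 change -1.93, SE 0.10, limma adjusted p = 0.0359). Carns1, carnosine synthase (1427146_PM_at), fell 3.84-fold (log2 change -1.94, SE 0.10, limma adjusted p = 0.0405). The largest changes among the 11 probe sets without a single gene name were a rise of 4.90 (1455869_PM_at) and a fall of 3.88 (1451632_PM_a_at) on the log2 scale.

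Other genes with large differences and no overlap between the groups missed the threshold over all probe sets. On the higher side, Cxcr6, a chemokine receptor of memory T and NK T cells, differed by 1.80 (limma adjusted p = 0.056), Rgcc by 1.68, Apol7a by 2.09, Stab2 by 1.42 and S100a9 by 2.53 (adjusted p between 0.0597 and 0.0795). Fcer1a, the IgE receptor chain of mast cells and basophils, differed by 1.42 but lay near background in the wild type arrays at 2.58. On the lower side, Kmo (log2 change -1.53), Pcp4 (-2.54), Irf8 (-1.32), Dnah8 (-1.36), Amy1 (-1.62) and Trim7 (-1.91) had adjusted p-values between 0.0634 and 0.0805. Amy1 lay at 2.86 on the transgenic arrays, at the level of the non-specific background controls there (2.95 and 2.85), so the size of its difference is not well measured. Rgl1 (-1.30), Lyl1 (-1.36), Fam167a (-1.43) and Srpk3 (-1.15) lay at 0.0809 to 0.081. Irf8 encodes a transcription factor of B and myeloid cells, and Lyl1 a helix-loop-helix factor of haematopoietic cells. The count of calls depended on the scaling between arrays: quantile normalization gave 870 probe sets, 402 higher and 468 lower, which included all 21, and every gene in this paragraph then passed (limma adjusted p from 0.00413 for S100a9 to 0.0497 for Srpk3). Without wild type mouse 1 or wild type mouse 2 no probe set passed limma (1631 and 1576 at an unadjusted p under 0.05), without transgenic mouse 1 4140 passed, and without transgenic mouse 2 19110 passed.

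**Figure D1:**
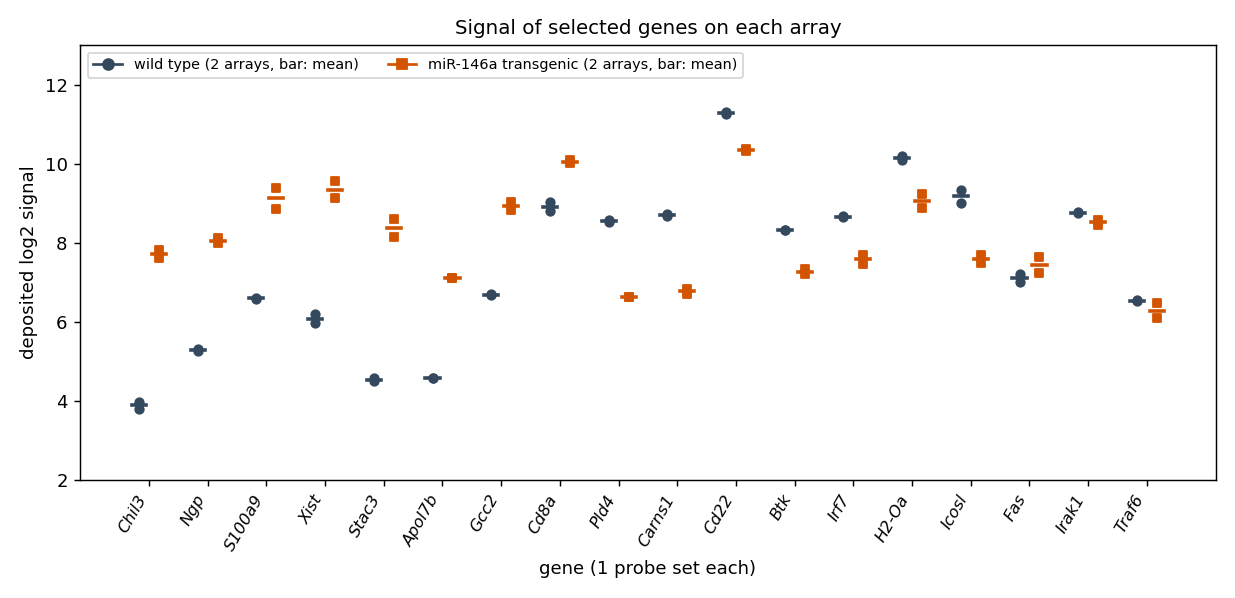
Deposited log2 signal (vertical axis) of 18 genes, 1 probe set each (horizontal axis), on the 2 wild type arrays (circles) and the 2 miR-146a transgenic arrays (squares), with a bar at each group's mean. Chil3, Ngp, Xist, Stac3, Apol7b and Gcc2 lay higher and Pld4 and Carns1 lower past the threshold, whereas Fas, Irak1 and Traf6 differed by 0.33, -0.24 and -0.26.

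Genes of resting follicular B cells were lower in the transgenic arrays as a group. Of 21 measured members, 20 were lower and 1 higher with no overlap between the groups, where chance gives no overlap for 33.3% of genes at 2 against 2. Over all probe sets 49.1% did not overlap in these arrays, 31.4% lower and 17.7% higher. These shares include dim probe sets, whereas list members are the brightest probe set of each gene. The median change was -0.121 over the 27022 probe sets kept by the filter on dim probe sets and -0.044 over all. The share without overlap was not computed for bright probe sets alone. Adjusted over all probe sets none passed, and adjusted over the list alone 18 were lower and 1 was higher. Btk, a kinase of B cell receptor signalling, differed by -1.07 (SE 0.10), Fcer2a, the IgE receptor CD23, by -1.02, Pou2af1, a B cell co-activator, by -1.10, and Cd22, an inhibitory co-receptor, by -0.94 (SE 0.10, limma adjusted p = 0.0935 for each). The member that was higher, named after its values were seen, was Klf2, a transcription factor of resting lymphocytes (0.37), which T cells also express. The median change was -0.94, a 1.92-fold lower signal (camera adjusted p = 5.9e-14 over 21 lists with a preset correlation between genes of 0.01). With an estimated correlation, where camera has 2 degrees of freedom, the camera adjusted p was 0.714. After quantile normalization the median was -0.82 and 12 members passed over all probe sets. In the same arrays the neutrophil and T cell lists had median changes of 1.04 and 0.31.

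Genes of antigen presentation by MHC class II, which B cells use to engage helper T cells, were also lower as a group. The median of 17 members was -0.63, with 16 lower without overlap, none past the threshold over all probe sets and 13 lower adjusted over the list alone. H2-Oa and H2-Ob, the chains of H2-O, differed by -1.08 and -1.01, Marchf1, a ubiquitin ligase that acts on class II, by -1.06, and Ctsh, a lysosomal protease, by -0.89. The camera adjusted p was 2.75e-10 with the preset correlation and the adjusted p = 0.714 with an estimated correlation. After quantile normalization the median was -0.549, and 7 members were lower past the threshold over all probe sets. The neutrophil and T cell lists moved the other way in these arrays, with medians of 1.04 and 0.31.

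Neutrophil, T cell, monocyte and natural killer cell transcripts were higher as groups, those of neutrophils most. Of 15 neutrophil genes 14 were higher without overlap, Chil3 and Ngp passed over all probe sets, and 11 passed adjusted over the list alone. S100a8 and S100a9, the calcium-binding proteins that abound in neutrophils, differed by 2.58 (SE 0.24) and 2.53 (SE 0.19), from 6.67 to 9.24 and from 6.59 to 9.12. The list's median was 1.04 (camera adjusted p = 2.79e-17; adjusted p = 0.714 with an estimated correlation). The median of 20 T cell genes was 0.31 (camera adjusted p = 1.71e-06; adjusted p = 0.714 with an estimated correlation), with none past the threshold over all probe sets and, over the list alone, 9 higher and 2 lower. Cd8a and Cd8b1, the chains of the CD8 co-receptor, differed by 1.14 and 0.74, and Ubash3a by 0.55, whereas Cd4 differed by -0.79. The wild type arrays also carried T cell transcripts, with Cd8b1 at 10.16 ± 0.06 (SD, n = 2) and Cd8a at 8.91 ± 0.15. Among 20 genes of monocytes, macrophages and dendritic cells (median 0.22), Ccr2 differed by 1.19 and Cd14 by 0.97, the 2 that passed over the list alone, and Lyz2 by 0.53 and Lyz1 by 0.37 (camera adjusted p = 3.21e-05; adjusted p = 0.714 with an estimated correlation). Among 15 natural killer cell genes (median 0.24), Eomes, a transcription factor shared with memory CD8 T cells, differed by 1.18 and Il2rb by 0.60, but Gzma by -0.96 (camera adjusted p = 0.00193; adjusted p = 0.714 with an estimated correlation). Over the list alone these 2 were higher and Gzma lower, but the other 2 probe sets of Il2rb differed by -0.16 and -0.20, and the mean of all 3 by 0.08. Without transgenic mouse 2 the medians were 0.09 for the monocyte list and 0.14 for the natural killer list, and after quantile normalization 0.322 and 0.415. Past the threshold over all probe sets, quantile normalization gave 8 neutrophil, 5 T cell and 2 monocyte list genes higher. For natural killer genes it gave 2 higher and 1 lower. Lists of lymph node stroma and of erythroid cells and platelets had medians of -0.02 and 0.03 and did not pass (camera adjusted p = 0.687 and 0.242), with Fn1 at 0.85 and Hba-a1, at 11.93 in the wild type arrays, at 0.34. The other probe sets of Hba-a1 were higher by 0.71 and 0.49.

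**Figure D2:**
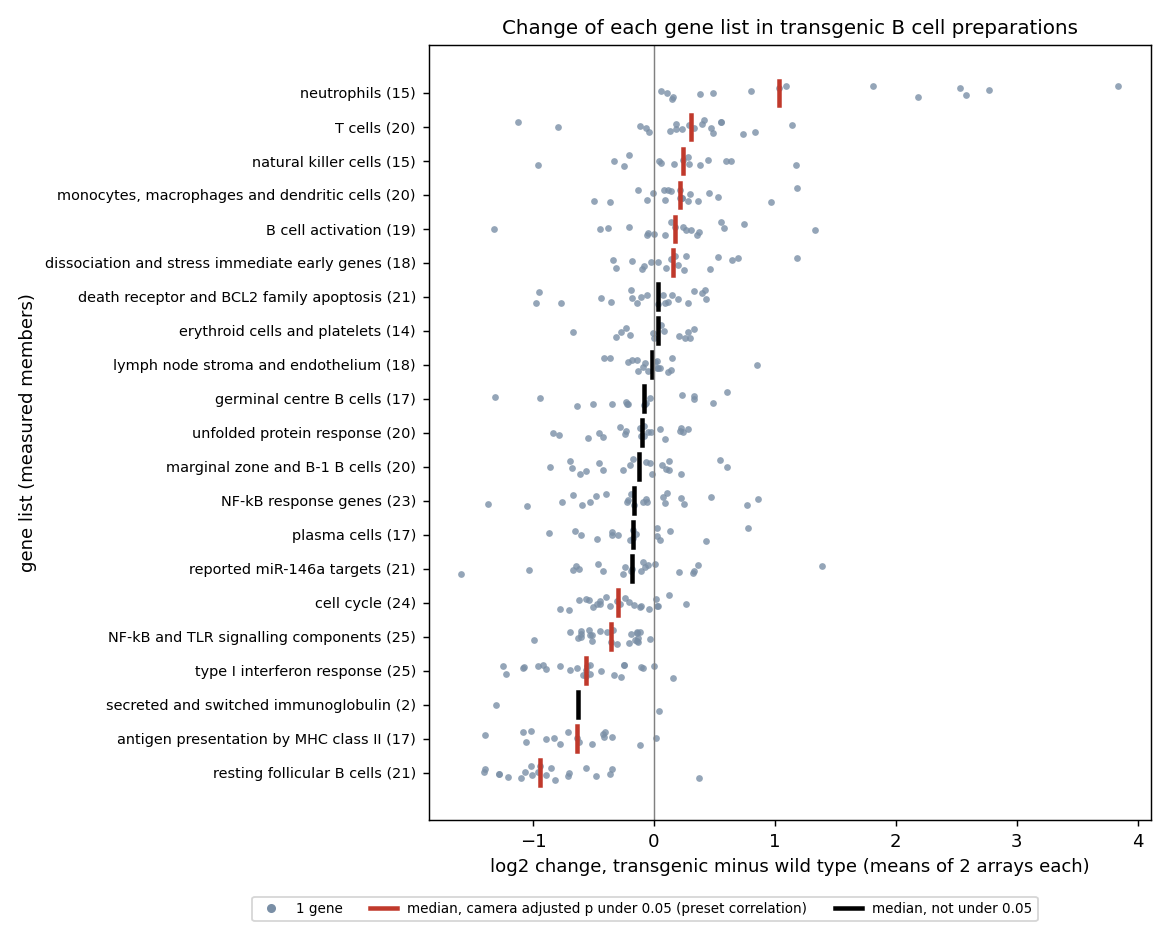
Log2 change of each measured gene (points, horizontal axis, transgenic mean minus wild type mean of 2 arrays each) in 21 gene lists fixed before the data were examined (vertical axis), with a bar at the list's median, red where the camera adjusted p with a preset correlation was under 0.05. Neutrophil genes had the highest median (1.04) and resting follicular B cell genes the lowest (-0.94).

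miR-146a is known to repress adaptors of Toll-like receptor signalling, so its reported targets were examined. None of 21 measured targets passed over all probe sets, and the list did not pass as a group (median -0.18, camera adjusted p = 0.242; after quantile normalization median -0.03, camera adjusted p = 0.613). After quantile normalization 1 target was higher and 1 lower past the threshold over all probe sets. The list's median was -0.044 without transgenic mouse 1 and -0.282 without transgenic mouse 2. Traf6 and Irak1, the best known targets, differed by -0.26 (SE 0.16, limma adjusted p = 0.525) and -0.24 (SE 0.11, adjusted p = 0.417). After quantile normalization these were -0.03 and -0.07, without transgenic mouse 1 -0.07 and -0.17, and without transgenic mouse 2 -0.45 and -0.31. Fas, the death receptor CD95, differed by 0.33 (SE 0.18, limma adjusted p = 0.486), from 7.10 ± 0.15 to 7.43 ± 0.29 (SD, n = 2 each), by 0.54 after quantile normalization and without transgenic mouse 1, and by 0.12 without transgenic mouse 2. Smad4 differed by -0.18 and Relb by -0.64, and after quantile normalization by -0.048 and -0.46. Numb differed by -0.05, a sign that turned after quantile normalization (0.13) and after median centring (0.0054). Adjusted over the list alone 4 targets passed, of which Icos and Irf5 were named after their values were seen. Icosl, the ligand of ICOS on B cells, was lower (log2 change -1.59, SE 0.16, from 9.17 to 7.58; -0.88 as the mean with a dimmer probe set that differed by -0.17), as were Irf5, an interferon regulatory factor (-1.03), and Irak2, a kinase of the same pathway as Irak1 (-0.67). Icos, a co-stimulator of T cells, was higher (1.39) on these arrays, where the T cell list was higher too. Resting follicular B cell genes were lower there (median -0.94). The falls of Icosl, Irf5 and Irak2 were not told apart from a lower share of B cell RNA. Sequences of 3' untranslated regions were not used here, so the enrichment of miR-146a seed sites, which the series description names, was not analysed here.

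Interferon and Toll-like receptor pathway genes were lower as groups. Of 25 type I interferon response genes 20 were lower without overlap and 1 higher. None passed over all probe sets, and 12 were lower adjusted over the list alone (median -0.56, camera adjusted p = 8.31e-09; adjusted p = 0.714 with an estimated correlation). Irf7, the regulator that amplifies interferon production, differed by -1.08 (SE 0.12), Mx1, an antiviral GTPase, by -1.22, and Oas2 and Oasl1, of the oligoadenylate synthetase family, by -0.92 and -0.90. Among 25 NF-kB and Toll-like receptor components 18 were lower without overlap (median -0.35, camera adjusted p = 5.77e-06; adjusted p = 0.714 with an estimated correlation). None passed over all probe sets, and the 4 that were lower over the list alone were Cd180 (-0.99) and its partner Ly86 (-0.51), which B cells express on their surface, Tab1 (-0.53) and Tlr7 (-0.70). NF-kB response genes did not pass as a group (median -0.16, camera adjusted p = 0.313; median 0.007 after quantile normalization -0.027 without transgenic mouse 1 and -0.326 without transgenic mouse 2). In that list Cd40 differed by -1.37, Nfkb2 by -0.67 and Nfkbie by -1.05, but Tnfaip3, an NF-kB inhibitor, by 0.47, and over the list alone 5 were lower and 1 was higher. The medians depended on scaling and on single transgenic arrays: after quantile normalization they were -0.16 for the components and -0.35 for interferon genes, and without transgenic mouse 1 -0.215 and -0.395, without transgenic mouse 2 -0.573 and -0.792, and both lists still passed camera with the preset correlation. After quantile normalization 5 interferon genes and 1 component were lower past the threshold over all probe sets, and none of either list was higher. Resting follicular B cell genes had a median of -0.94 in these arrays as deposited.

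Lists for B cell states, survival and stress differed in direction, and most did not pass as groups. Germinal centre genes had a median of -0.08 (camera adjusted p = 0.674), with Myo1e at -1.31, the 1 member past the threshold over the list alone, Mef2b at -0.63, Gcsam at 0.49, Tnfsf9 at 0.34 and Bcl6, the germinal centre regulator, at -0.50 (SE 0.17), with a dimmer probe set at 0.19. Bcl6 differed by -0.29 without transgenic mouse 1 and by -0.72 without transgenic mouse 2. Plasma cell genes had a median of -0.18 (camera adjusted p = 0.277), and the 2 that passed over the list alone were Jchain (-0.65), the joining chain of secreted antibodies, and Txndc5 (-0.87), whereas Cd28, better known from T cells, differed by 0.78 and Derl3 by -0.34. Marginal zone and B-1 genes had a median of -0.12 (camera adjusted p = 0.595), with Plac8 at -0.86, Dtx1 at -0.61, Ahnak at 0.61 and Ctla4 at 0.54, and none passed over the list alone. Of the immunoglobulin list only 2 members were measured, Iglv1 (-1.30) and Igha (0.04), and it did not pass (median -0.63, camera adjusted p = 0.277). Among 21 apoptosis genes (median 0.04, camera adjusted p = 0.674), Bmf (-0.95), Bak1 (-0.98) and Casp9 (-0.77), all promoters of cell death, were lower over the list alone, though a dimmer probe set of Casp9 differed by 0.16, and Pmaip1 differed by 0.42. The activation list passed as higher (median 0.17, camera adjusted p = 0.00193; adjusted p = 0.714 with an estimated correlation), with Nfil3 at 1.33, Cd44 at 0.58 and Il4ra at 0.55, genes that T cells also express, and Irf8 at -1.32. Over the list alone 5 of its members were higher and 2 lower. Its median was 0.34 after quantile normalization, 0.29 without transgenic mouse 1 and 0.135 without transgenic mouse 2. Stress and immediate early genes, which mark handling of cells, passed as higher (median 0.16, camera adjusted p = 0.0011; adjusted p = 0.714 with an estimated correlation). The 4 of them that passed over the list alone were the heat shock protein Hsph1 (1.18), Klf6 (0.69), Jun (0.53) and Atf3 (0.65). The stress list's median was 0.29 after quantile normalization, 0.199 without transgenic mouse 1 and 0.112 without transgenic mouse 2. The unfolded protein response did not pass (median -0.09, camera adjusted p = 0.313), with Atf6 at -0.83, its 1 member past the threshold over the list alone, Syvn1 at -0.78, Ddit3 at -0.55 and Herpud1 at -0.45. Cell cycle genes passed as lower (median -0.29, camera adjusted p = 0.0195; adjusted p = 0.884 with an estimated correlation), with none past the threshold over the list alone. Cdc20 differed by -0.62, Birc5 by -0.70, Bub1b by -0.50 and Mcm6 by -0.47. The cell cycle median was -0.04 without transgenic mouse 1 and -0.518 without transgenic mouse 2. After quantile normalization it was -0.08 (camera adjusted p = 0.12).

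List medians near 0 depended on scaling and on single arrays, and several turned sign. The plasma cell median was 0.018 without transgenic mouse 1, -0.347 without transgenic mouse 2 and -0.076 after quantile normalization. That of the unfolded protein response was 0.033, -0.259 and 0.062 in the same order, and that of apoptosis genes 0.17, -0.138 and 0.084. Germinal centre genes had -0.052, -0.167 and -0.015, marginal zone and B-1 genes -0.052, -0.12 and 0.004, stroma 0.019, -0.079 and 0.005, and erythroid cells and platelets 0.119, -0.033 and 0.128. Other probe sets of some named genes also differed by other amounts than the brightest one. For Klf6 the other 2 bright probe sets differed by 0.31 and 0.06, for Jun the second by 0.13 and for Txndc5 by -0.26, where all but that at 0.31 overlapped between the groups. The other 2 of Smad4 differed by -0.36 and -0.03. For Ccr2 the others differed by 0.20, 0.70 and 0.93, for Cd8a by 0.64 and 1.90, and 1 other probe set each of H2-Ob by -0.33, Marchf1 by -0.67, Rgl1 by -0.68, Cd44 by 0.33, Herpud1 by -0.255 and Bub1b by -0.29.

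All mice were labelled male, and sex-linked transcripts were given as values. Xist lay at 6.07 ± 0.16 in the wild type and 9.34 ± 0.30 in the transgenic arrays (SD, n = 2 each), and its second called probe set (1427262_PM_at) rose by 2.29. Y-linked genes were present in both groups. Eif2s3y lay at 8.31 in the wild type and 7.90 in the transgenic arrays (log2 change -0.41, SE 0.12, limma adjusted p = 0.274). Kdm5d differed by -0.21 (SE 0.15, limma adjusted p = 0.569), and Uty by -0.01, a sign that turned after quantile normalization (0.03).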

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

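One group of control probe sets, which the comparisons do not use, was higher on both transgenic arrays than on both wild type arrays. The 11 non-specific background probe sets averaged 2.95 and 2.85 on the transgenic arrays and 2.83 and 2.84 on the wild type arrays, a difference of 0.064. Groups of 2 arrays are too small for a test of outlying arrays, and chance gives a separation in either direction to 33.3% of measures at 2 against 2. Of all probe sets 49.1% showed one, 31.4% lower and 17.7% higher. The other control groups, given as values, were the hybridization spikes (8.71 and 9.07 against 9.27 and 9.40), the poly-A spikes (6.86 and 6.88 against 7.37 and 7.45) and 18S ribosomal RNA (9.94 and 10.8 against 9.96 and 9.64). Both spike groups lay lower on both transgenic arrays than on both wild type arrays, with differences of -0.444 and -0.544. This shift goes with the groups, and its effect on the comparisons was not tested.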

How the results depend on the processing

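The number of probe sets past the threshold depended on the processing. Against 21 (17 higher, 4 lower) as deposited, quantile normalization gave 870 (402 higher, 468 lower), median centring 614 (189 higher, 425 lower), the filter on dim probe sets 51 (38 higher, 13 lower, of 27022 tested) and an adjusted p under 0.1 139 (65 higher, 74 lower), and each of these held all 21. The trended and robust eBayes gave 26 with 7 lower, and requiring a log2 change of at least 1 left 21. The fit with the mouse number as a replicate block gave 15, 13 higher and 2 lower, and 14 of them were among the 21; Gcc2, Carns1 and Pld4 then missed the threshold. The 2 groups share only mouse numbers, and the block changed no list's call. Leaving out 1 array gave 0 to 19110 probe sets, 0 to 4278 higher and 0 to 14832 lower: 0 without either wild type array, 4140 without transgenic mouse 1 and 19110 without transgenic mouse 2. With 1 array left in a group, that array is assumed to vary like the other group. The wild type arrays differ little from each other, so the fits that rest on their spread alone call many more probe sets. Camera called 6 lists higher and 5 lower with the preset correlation and 0 and 0 with an estimated one, where it has 2 degrees of freedom. The other alternatives and left-out arrays gave 6 higher and 4 or 5 lower. Cell cycle was lost after quantile normalization, without transgenic mouse 1 and with the dim filter, where the immunoglobulin list passed instead. That filter, at 4.10, removed Igha (3.18 in the wild type and 3.22 in the transgenic arrays) and left only Iglv1 (-1.30). The immunoglobulin call therefore rests on 1 gene and says nothing about a list. The list of reported miR-146a targets passed under none of the alternatives (camera adjusted p 0.186 to 0.884). Camera's direction turned, without a call, for stroma after quantile normalization (adjusted p = 0.891) and for germinal centre genes after the dim filter (adjusted p = 0.966). Over left-out arrays, camera's adjusted p was 0.513 to 0.929 for stroma and 0.245 to 0.939 for apoptosis, with a turned direction without transgenic mouse 1 and mouse 2, respectively. Of 1119 gene values recomputed, 9 changed sign, in 4 genes near 0: Numb (0.13 after quantile normalization, 0.0054 after median centring, 0.037 as the mean of its probe sets), Uty (0.033 after quantile normalization, 0.042 after median centring, -0.20 to 0.17 over left-out arrays), Kdm5d (0.13 as the mean of its probe sets) and Igha (-0.017 to 0.10 over left-out arrays). The cause of these changes was not tested.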

Other observations

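All tests in this part except that of the second B cell panel and that of neighbouring genes were chosen after the result was seen. For neighbouring genes, leaving out pairs with like symbols was not part of what was fixed in advance. Some genes outside the lists were chosen after their values were seen, so they cannot test a T cell or myeloid pattern. Chil4, Il4, Fpr2, Gzmm, Apol7c, Cybb and Oas1g all missed the threshold over all probe sets. Chil4, a relative of Chil3, was higher by 2.03 (limma adjusted p = 0.0871), Il4, a cytokine of helper T cells, by 1.58 (adjusted p = 0.0806), Fpr2, a formyl peptide receptor of neutrophils, by 1.01 and Gzmm, a granzyme of cytotoxic lymphocytes, by 1.37 (adjusted p = 0.0935 each). Apol7c was higher by 2.51 (adjusted p = 0.081), beside Apol7b (2.54) and Apol7a (2.09), so 3 members of 1 gene family lay higher by over 2; shared sequence between the probe sets of such relatives was not tested. On the lower side Cybb, a subunit of the phagocyte oxidase that B cells also express, differed by -1.44 (adjusted p = 0.081) and Oas1g by -1.61 (adjusted p = 0.0935). A second, dimmer probe set of Tnfaip3 was higher by 1.78 and the bright one by 0.47.

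B cell genes were lower and neutrophil genes higher in the transgenic preparations. The neutrophil and T cell medians differed by 0.725 (two-sided permutation p over genes = 0.00145, genes are not independent), so these lists did not change alike. This gap cannot decide whether a lower share of B cells raised every other cell type alike. The reason is that even probe sets of 1 gene changed by unlike amounts, for Cd8a by 0.64, 1.14 and 1.90. The lower signal of transgenic mouse 1 as the whole cause is argued against by the medians without it. These were -0.759 for B cell genes and 1.191 for neutrophil genes. Dilution of B cell transcripts by other cells stays open: in a second panel of B cell genes, fixed before its values were seen, 12 of 13 measured genes were lower with a median of -0.847, which is consistent with a lower share of B cell RNA, though Ly6d was higher by 0.89. The magnetic separation should remove T cells and neutrophils, yet S100a8 reached 9.24 and Cd8b1 10.9 on the transgenic arrays; none of the T cell or neutrophil list's members is in another list. A change within B cells caused by the transgene was not tested apart from this.

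Xist was 9.64-fold higher in preparations labelled male. Preparations from female mice only are argued against, because Eif2s3y lay at least 4.849 above the non-specific background on both transgenic arrays. Female cells mixed into mostly male preparations may account for the rise, but this stays open: Eif2s3y differed by -0.412 (95% limits -0.716 to -0.108, adjusted p = 0.273; -0.24 after quantile normalization), Kdm5d by -0.21, and 4 X-linked genes that escape silencing had a median change of 0.016. An effect of the transgene on Xist in male cells was not tested.

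Stac3, Gcc2, Apol7b and Mfap1a, of whose 3 probe sets 1 passed the threshold, rose by over 4-fold and share no list. A single chromosome segment of another strain that holds all of these genes is argued against. At most 2 of the 9 called genes lie on 1 chromosome, and Apol7b lies on chromosome 15 and Mfap1a on chromosome 2. The 2 that share a chromosome are Stac3 and Gcc2, both on chromosome 10, so a segment that holds these 2 stays open. The 11 called probe sets without a single gene name were not placed. Segments of another strain in general stay open. Among the 100 genes with the smallest p, 13 pairs lay within 10 genes of each other against a median of 6 in 10000 random draws (one-sided permutation p = 0.0069). This met the criterion fixed in advance. Without pairs whose symbols share their first 3 letters, an exclusion that was not fixed in advance, 7 remained against 5 (one-sided permutation p = 0.323). A sequence difference under the probes could also raise 1 probe set, but only 2 second probe sets of a called gene were bright enough, both of Mfap1a. They changed by 0.268 and 0.79 of the called change, so 0 of the 2 stayed nearly flat, which is too few to decide. The real grouping gave 21 probe sets and the highest of the 2 other splits of the 4 arrays gave 0, with 1 of 3 splits as large as the real one; 3 splits are too few for a share under 0.05.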
